A study of Mus musculus with 4 samples.

How the data were processed

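Tissue from the remote area of infarcted hearts, away from the infarct, in 2 mice was compared with uninjured hearts of 2 mice, all C57BL/6. Groups and replicate numbers were taken from the labels. Per the labels' protocols, total RNA was purified with a Qiagen kit, polyadenylated RNA was made into Illumina libraries, and these were sequenced on a GAII as single-end reads of 50 bp. Whether the libraries keep the strand is not given in the sources used here, so reads of a gene and of an overlapping antisense gene cannot be told apart, and reads shared by paralogs or near-identical copies leave such genes uncertain.

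The authors deposited 2 tables. The first holds raw counts per Ensembl gene, whole numbers that were not normalized, as deposited for 21552 genes; the aligner, the counter and the annotation release are not given in the sources used here. The second holds the percent inclusion of exons and the percent use of alternative splice sites in each library, as deposited for 124326 events, each with corrected inclusion and exclusion reads. Coordinates are on mm9, the genome build named in the submitters' processing notes. The tool that made the events is not given in the sources used here. The percent values equal 100 times inclusion over inclusion plus exclusion reads within 0.05 points in 100% of events with at least 10 reads. Symbols were joined by Ensembl identifier to GENCODE M21, which matched 20450 genes and left 1102 unmatched, and 4014 genes had no counts in any library. Each column was tied to its library by the name the labels give it.

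Library totals ranged from 35715115 to 70885393 counts and the common biological coefficient of variation between mice of a group was 19.3%. Across genes the log2 CPM of library pairs had Pearson correlations of 0.918 to 0.987. Genes are not independent replicates, so these only describe the libraries. The labels give no sequencing or library batch.

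Gene counts were tested in edgeR 4.0.16 with TMM normalization, filterByExpr by group, robust dispersions and the quasi-likelihood F-test, in R 4.3.3, which left 13905 genes. Genes were called at a Benjamini-Hochberg adjusted p below 0.05. Standard errors of log2 fold changes were derived from the test, as the absolute log2 fold change divided by the square root of its F statistic. CPM use the TMM library sizes. With 2 mice per group the fit has 2 residual degrees of freedom and borrows its spread from all genes. A list of genes was tested if at least 5 of its members were, with camera at a preset inter-gene correlation of 0.01 over 31 lists, beside camera with an estimated correlation and fry, in limma 3.58.1. Camera compares a list with all other genes, whereas fry asks whether its members move one way. With an estimated correlation camera also takes its p from the 2 residual degrees of freedom, so few lists could pass for that reason alone. The lists cover cardiomyocyte stress, contraction, channels, matrix, energy metabolism, cell cycle, immune response, stress responses, ribosomes, splicing, the clock, and markers of other cell types. List symbols were matched to current symbols, or to a unique RefSeq synonym. Kcnj11, Ighm, Hbb-b1, Hbb-b2, Muc16, mt-Nd4l, Rpl24, Rps18 and Qki were not matched.

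Splicing events were tested if each library had at least 10 reads and each form at least 5 reads over all libraries, after rounding the corrected reads to whole numbers. That left 5490 exons and 2593 splice sites. The edgeR quasi-likelihood test of the form-by-group interaction had a term for each library. A second test was limma on the logit with 0.5 reads added to each form. Added after the data were seen were limma with weights for binomial error and overdispersion, at an estimated or a set overdispersion, limma with binomial weights, a DESeq2 likelihood-ratio test, and thinning of the reads to the shallowest library of each event. The overlap of genes called in level and in splicing could not be computed, since no event was called by edgeR.

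The groups, tests, filters, gene lists and the rule for named genes were fixed before the data were examined, as were the first of the other settings named below. That rule took the 8 genes called higher and the 8 called lower with the largest fold change, a mean of at least 5 CPM and no overlap between groups. It also took up to 4 members of each list with the smallest p. Some genes that the rule takes are not reported here. For splicing it took the 6 called events in each direction with the largest difference or, as none was called, the 4 with the smallest p in a list of genes with splicing known in the heart. The first settings were other normalization factors and filters, DESeq2 1.42.0, limma-voom, a 2-fold threshold, the replicate number as a block and leaving out each library. Settings added after the data were seen were library totals as the scale, leaving out mitochondrially encoded genes, removal of the trend with transcript length or GC content, legacy=FALSE in edgeR, and DESeq2 with each library left out. Length and GC were those of the longest GENCODE M21 transcript, known for 98.8% of the genes tested.

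The edgeR tests, camera and the limma fits of events were first run on simulated data with the real library sizes or event reads; DESeq2, limma-voom and fry were not. Of 50 genes each changed by 1.5-, 2-, 4- and 8-fold edgeR recovered 2, 24, 46 and 50, with 13 false calls beside 122 true ones, which is 9.63% and above the nominal 5%. Camera recovered 2 of 2 lists changed by 1.5-fold, with 0 false calls over 31 lists. Genes were simulated independently, whereas the estimated correlation within the real lists reached 0.972 (oxidative phosphorylation). The simulation therefore does not test camera on correlated lists. Of 50 events each changed by 10, 20, 30 and 40 percentage points edgeR and unweighted limma recovered 0, overdispersed limma recovered 1, 3, 20 and 36 with 1 false call, and binomial limma recovered 2, 6, 19 and 27 with 45 false calls beside 54 true ones. All simulated events had the same overdispersion, as overdispersed limma assumes, which favours that fit. Only events of intermediate inclusion were changed. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. Microexon events were left out of the splicing test because neither uninjured library has a value for them.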

Results

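The data set compares the remote area of infarcted hearts, the myocardium away from the infarct, in 2 mice with uninjured hearts of 2 mice, all C57BL/6. Infarcts had been made by tying off the left anterior descending coronary artery for good, and the tissue was taken 7 days later. Polyadenylated RNA from each heart was sequenced, and reads were counted for 21552 genes. The totals were 46232326 and 35715115 counts in infarcted replicates 1 and 2, and 53944859 and 70885393 in uninjured replicates 1 and 2. Genes of the mitochondrial genome took 42.0% and 36.7% of the counts in the infarcted libraries and 48.4% and 41.4% in the uninjured ones. A second set of values gave the inclusion level of alternative exons and splice sites in the same 4 libraries. The question put to both was which mRNAs, and which exons, differ in remote myocardium 1 week after infarction.

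The samples labelled as remote area of infarcted hearts carried far more mRNA for matrix proteins. Scar or border tissue in them was not excluded. Cthrc1, a secreted protein of activated fibroblasts (ENSMUSG00000054196), was 244-fold higher, at 29.3 ± 11.9 CPM against 0.118 ± 0.00974 CPM (SD, n = 2 per group). Tenascin C (Tnc) was 99.5-fold higher, at 111 ± 30.6 against 1.13 ± 0.240 CPM, and the collagen cross-linking enzyme Lox was 59.3-fold higher. Ltbp2, which binds fibrillin in the matrix, rose 43.7-fold, the fibril-associated collagen Col12a1 rose 41.5-fold, and periostin (Postn) rose 40.6-fold, to 1140 ± 454 CPM. Sprr1a, a cornified-envelope protein also made by stressed cardiomyocytes, rose 73.8-fold. The largest falls were smaller. The lipase Ces1d went from 99.9 ± 31.5 to 10.6 ± 0.743 CPM, 9.39-fold lower, and the potassium channel subunit Kcnv2 was 5.84-fold lower. Gal3st3, Smco1, Lingo3, Tcf15 and the mitochondrial carrier Ucp3 were 5.13-, 4.64-, 4.49-, 4.44- and 4.22-fold lower. The edgeR adjusted p-values of these genes ran from 5.42e-08 for Tnc, Lox, Ltbp2 and Col12a1 to 0.0439 for Ucp3. Both infarcted libraries lay outside the range of both uninjured ones in each, which was a condition for choosing these genes.

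Over all 13905 genes tested by edgeR, 2546 were higher and 2037 lower at an adjusted p below 0.05. Among them 1765 were higher and 769 lower by at least 2-fold, and 659 and 79 by at least 4-fold. The infarcted and uninjured libraries did not overlap for 70.0% of the genes, where chance gives 33.3%. With library totals alone as the scale the split was 4386 higher and 786 lower, the median of all genes moving from 0.02 to 0.36 on the log2 scale. The count rested on uninjured replicate 2: without it edgeR called 102 genes higher and 8 lower, with 4299 genes at an unadjusted p below 0.05, and DESeq2 called 1167 and 600. In that edgeR fit most of the named genes lost their call. The genes called higher and lower with all libraries had median log2 fold changes of 1.253 and -0.72 there, against 1.255 and -0.88 without infarcted replicate 2. Their signs were bound to hold, since the groups did not overlap for any of the 4583 called genes. Without infarcted replicate 2 the lower count was 1251, and without uninjured replicate 1 the higher count was 1691. Of 31 fixed gene lists camera called 10 higher and 8 lower, 0 and 0 with an estimated correlation, and fry called 3 higher, the non-collagen matrix, TGF-beta and macrophage lists.

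**Figure D1:**
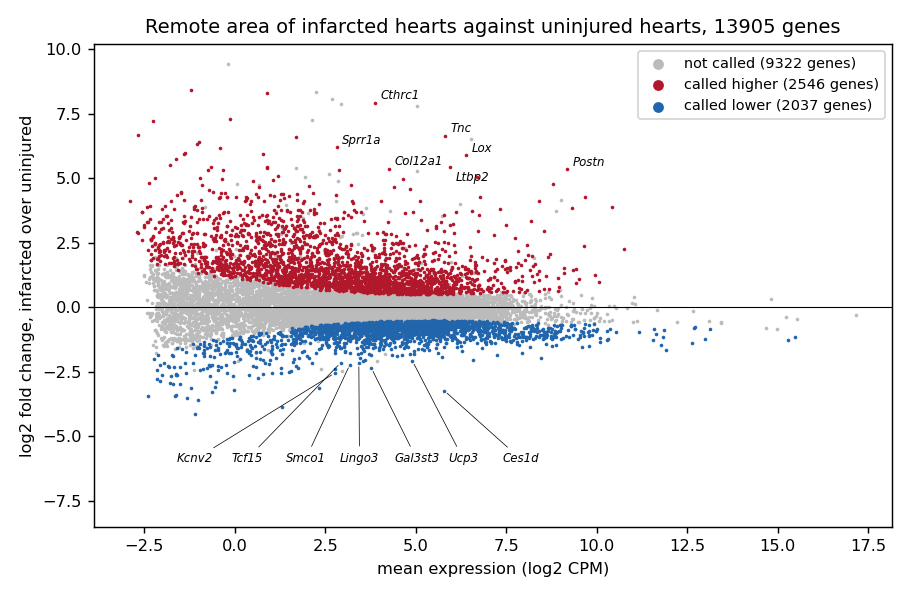
Each point is 1 of 13905 genes, with its mean expression in log2 CPM on the horizontal axis and its log2 fold change, infarcted over uninjured, on the vertical axis. The 2546 genes called higher reach larger changes than the 2037 called lower, and the labelled genes are those the text names for large changes among genes with a mean of at least 5 CPM.

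The extracellular matrix was the group with the largest change. Of 19 collagens 18 rose and 0 fell, with a median log2 fold change of 3.19. Col3a1 and Col1a1, the main fibrillar collagens of the heart, rose by 3.90 ± 0.26 and 4.28 ± 0.29 (log2 ± SE), to 2586 ± 41.7 and 1547 ± 475 CPM (SD, n = 2), and Col5a2 rose by 3.82 ± 0.24. Of 34 other matrix genes 31 rose, with a median of 3.25, Mfap4, a microfibril protein, by 3.69 ± 0.21. The TGF-beta and myofibroblast list rose in 17 of 20 members (median 1.94), with connective tissue growth factor (Ccn2) up by 4.12 ± 0.29 and the ligand Tgfb3 by 2.26 ± 0.20. Fibroblast markers moved less: 10 of 17 rose, with a median of 1.18, led by Mfap5 at 3.20 ± 0.21, Serpinf1 at 2.01 ± 0.19, Lum at 1.76 ± 0.19 and Cd248 at 1.71 ± 0.19. These lists share members: Mfap5 and Mmp2 are also matrix genes, and Ltbp2, Ccn2, Postn and Cilp are in both the matrix and TGF-beta lists. The 15 fibroblast markers in no other list had a median of 0.87. Counts adjusted over the list alone were 18 collagens, 32 matrix genes, 19 of the TGF-beta list and 12 fibroblast markers higher, with 1 fibroblast marker lower. Camera called the 4 lists higher (adjusted p of 3.56e-43, 1.50e-71, 9.50e-26 and 1.37e-07), and none passed with an estimated correlation (adjusted p = 0.359, 0.0703, 0.112 and 0.489). The latter version rests on the 2 residual degrees of freedom, so its lost calls cannot be laid to correlation alone. The non-collagen matrix and TGF-beta lists had estimated correlations of -0.005 and -0.048, below the preset 0.01. Without uninjured replicate 2 edgeR called 9 collagens, 18 matrix genes, 4 TGF-beta genes and 5 fibroblast markers, and DESeq2 called 18, 31, 16 and 10. Without infarcted replicate 2, 3 fibroblast markers were called lower.

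In the muscle cell programme, stress genes rose and parts of the adult machinery fell. Of 16 stress and fetal genes 10 rose and 0 fell, with a median log2 fold change of 2.08. Gdf15, a stress cytokine, rose by 2.15 ± 0.34, the calcineurin regulator Rcan1 by 1.42 ± 0.23, to 173 ± 48.8 CPM (SD, n = 2), and the ankyrin-repeat protein Ankrd2 and the actin-binding protein Xirp1 by 3.18 ± 0.52 and 1.22 ± 0.22. Of 20 adult contractile genes 8 fell and 1 rose (median -0.39, or -0.0396 with library totals). Cardiac troponin I (Tnni3) fell by 1.47 ± 0.29, from 5177 ± 1752 to 1874 ± 120 CPM, the ventricular light chains Myl2 and Myl3 fell by 1.37 ± 0.29 and 1.28 ± 0.28, and telethonin (Tcap) fell by 1.23 ± 0.27. Tnni3, Myl2, Myl3 and Tcap were each higher in uninjured replicate 2 than in uninjured replicate 1, Tnni3 at 6416 against 3938 CPM. With the transcript length trend removed, 8 contractile genes were called lower and 1 higher (median -0.42). The falls of single contractile genes under that correction are not reported here. Among calcium-handling and channel genes 11 of 24 fell and 2 rose (median -0.56). Kcnip2, the partner of the transient outward potassium channel, fell by 2.03 ± 0.27, Kcnv2 fell by 2.55 ± 0.25, and the inward rectifiers Kcnj3 and Kcnj2 fell by 1.10 ± 0.19 and 0.93 ± 0.18. Adjusted over the list alone, 10 stress genes were higher, 8 contractile genes lower and 1 higher, and 12 channel genes lower and 2 higher. Camera on the edgeR counts gave adjusted p of 5.04e-06, 0.00570 and 0.000593. With an estimated correlation the adjusted p was 0.447, 0.590 and 0.489. The stress list shares Nppa, Myl4, Myl7 and Mybphl with the atrial markers, and of these Myl4, Myl7 and Mybphl were over 10-fold higher in infarcted replicate 2 than in any other library. Without that library its median was 1.51, with 5 contractile and 7 channel genes called lower. With infarcted replicate 1 left out 4 contractile genes were called lower, and with uninjured replicate 1 left out 6 stress genes and 1 channel gene were called higher. With infarcted replicate 2 left out 1 channel gene was called higher. With uninjured replicate 2 left out edgeR called 0 stress, 0 contractile and 1 channel gene, against 12 higher, 8 lower and 10 lower at an unadjusted p below 0.05 and 8, 6 and 7 called by DESeq2.

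Most genes of mitochondrial energy metabolism encoded in the nucleus were lower in infarcted hearts. All 43 nuclear-encoded genes of oxidative phosphorylation fell, with a median log2 fold change of -1.13, among them Cox7a1, a subunit of cytochrome oxidase, which fell by 1.95 ± 0.27, from 564 ± 159 to 146 ± 38.9 CPM (SD, n = 2), and Ndufa5, Ndufs3 and Ndufs4 of complex I, which fell by 1.36 ± 0.25, 1.26 ± 0.23 and 1.25 ± 0.22. Fatty acid uptake and oxidation fell in 22 of 28 members (median -0.997), with Eci1, Hadh, Cpt2 and Mlycd falling by 1.44 ± 0.22, 1.42 ± 0.23, 1.29 ± 0.21 and 1.55 ± 0.25. The tricarboxylic acid cycle fell in 18 of 21 (median -0.82; Sdhb fell by 1.20 ± 0.25, Sdhc by 1.14 ± 0.23, Idh3b by 1.11 ± 0.22 and Sucla2 by 1.05 ± 0.22), and branched-chain amino acid catabolism in 16 of 17 (median -0.96; Mccc2 fell by 1.31 ± 0.20, Bckdhb by 1.29 ± 0.21, Auh by 1.22 ± 0.19 and Ppm1k by 1.16 ± 0.18). Glycolysis and glucose uptake was mixed, with 6 of 22 lower and 2 higher (median -0.32, or 0.02 with library totals): Ldhb, Slc2a4 and Pfkfb1 fell by 1.36 ± 0.25, 1.19 ± 0.22 and 1.73 ± 0.25, while the platelet phosphofructokinase Pfkp rose by 1.25 ± 0.19. Of 12 mRNAs encoded by mitochondrial DNA 3 fell (median -0.52), namely mt-Nd3, mt-Co3 and mt-Co2 by 1.64 ± 0.31, 1.25 ± 0.36 and 1.14 ± 0.37; mt-Nd1 was not called, at -0.85 ± 0.32. Adjusted over the list alone the lower counts were 43, 22, 19, 16, 7 and 3 in that order, with 2 glycolysis genes higher. Camera on the edgeR counts called the 6 lists lower, with adjusted p of 6.83e-20, 9.70e-11, 1.28e-08, 1.55e-09, 0.0376 and 0.00689, and with an estimated correlation the adjusted p was 0.503, 0.489, 0.489, 0.359, 0.775 and 0.568.

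The 2 uninjured libraries differed in these lists. Oxidative phosphorylation genes lay 0.63 higher on the log2 scale in uninjured replicate 2 than in uninjured replicate 1, fatty acid genes 0.41 higher and tricarboxylic acid cycle genes 0.33 higher. Short transcripts as a whole were higher in uninjured replicate 2: genes whose longest transcript has 700 nucleotides or fewer had a median difference, replicate 1 minus replicate 2, of -0.49, and genes over 6000 nucleotides one of 0.25. Infarcted over uninjured, the same classes had medians of -0.63 and 0.27. With that trend removed the oxidative phosphorylation median was -0.65, with 43 of 43 members below 0 and 31 called lower. The mitochondrially encoded and glycolysis lists were then no longer called. The mitochondrially encoded median was -0.001, with 6 members below 0, 6 above and 0 called, and the glycolysis median was -0.15. Without uninjured replicate 2 the oxidative phosphorylation median was -0.78 and edgeR called 0 of the 43 members, with 43 at an unadjusted p below 0.05 and 39 called by DESeq2. Its calls were also 0 in each of the other 5 metabolic lists, where DESeq2 called 19 fatty acid, 12 tricarboxylic acid cycle, 11 branched-chain, 7 glycolysis and 3 mitochondrially encoded genes lower, and 22, 19, 16, 7 and 4 had an unadjusted p below 0.05 in edgeR. Without infarcted replicate 2 fewer tricarboxylic acid cycle members were called lower, though 21 of 21 lay below 0 (median -0.88). Mitochondrially encoded genes called lower numbered 5 without infarcted replicate 1 and 1 without infarcted replicate 2 or uninjured replicate 1, and 1 glycolysis gene was called higher in either of the last 2 fits. Of the fatty acid genes 2 were called higher without infarcted replicate 1, and 1 mitochondrially encoded gene was called higher without uninjured replicate 1. Both lists that lost their call with the length trend removed lost it without infarcted replicate 2 as well, the mitochondrially encoded list also without uninjured replicate 1 and glycolysis also without uninjured replicate 2.

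Cell cycle and innate immune genes were higher in infarcted hearts. Of 24 cell cycle genes 20 rose, with a median log2 fold change of 2.72 (1.89 without infarcted replicate 1 and 3.13 without infarcted replicate 2); the mitotic cyclin Ccnb1 rose by 4.17 ± 0.40 to 6.22 ± 2.83 CPM (SD, n = 2), and Plk1, Birc5 and Cdc20 by 3.53 ± 0.37, 3.17 ± 0.40 and 2.81 ± 0.35. Of 25 macrophage and monocyte markers 22 rose (median 1.48), with Gpnmb up by 3.78 ± 0.28, Lgals3 by 3.35 ± 0.24, cathepsin S (Ctss) by 2.55 ± 0.20 and Cd68 by 2.12 ± 0.21. Interferon-stimulated genes rose in 11 of 20 members (median 0.84; Mx1 by 2.72 ± 0.40, Oas2 by 1.22 ± 0.24, Oasl2 by 1.18 ± 0.20 and Ddx58 by 1.17 ± 0.23). Of 5 neutrophil markers tested Csf3r and Mmp9 rose, by 2.05 ± 0.31 and 1.21 ± 0.29, and S100a8 and S100a9 were not called, at 1.76 ± 0.66 and 2.02 ± 0.70 (list median 2.02, or 0.75 without infarcted replicate 2). Adjusted over the list alone 22 cell cycle, 23 macrophage, 13 interferon and 4 neutrophil genes were higher. The adjusted p of camera on the edgeR counts was 2.37e-14, 1.49e-22, 0.00102 and 0.0400, and with an estimated correlation the adjusted p was 0.489, 0.282, 0.438 and 0.489. Cell cycle genes lay 1.07 higher on the log2 scale in infarcted replicate 1 than in infarcted replicate 2, and neutrophil markers 2.10 higher in infarcted replicate 2. The neutrophil call ended with library totals alone and with a GC trend removed. Left without uninjured replicate 2, edgeR called 0 cell cycle, 3 macrophage, 0 interferon and 0 neutrophil genes, with 19, 22, 10 and 2 at an unadjusted p below 0.05 and 20, 21, 5 and 1 called by DESeq2; without uninjured replicate 1 it called 6 interferon genes and 1 neutrophil gene, and without infarcted replicate 1 it called 5 neutrophil genes.

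Lymphocyte and antigen presentation genes did not pass as lists. Of 12 lymphocyte markers the cytokine receptor Il7r rose by 1.89 ± 0.45 and the B cell receptor subunit Cd79b fell by 1.58 ± 0.51, while Ms4a1 and Cd79a were not called, at -1.56 ± 0.62 and -1.46 ± 0.57 (median of the list -0.65, or -1.36 without infarcted replicate 1 and -0.21 without infarcted replicate 2). Of 9 MHC class II genes Cd80 and Cd86, which are costimulatory ligands, rose by 2.23 ± 0.47 and 0.86 ± 0.30. Ciita and H2-Eb1 were not called, at 0.85 ± 0.35 and -0.47 ± 0.24, and the median of the list was -0.08 with a mean of 0.27 and a test direction upward; without uninjured replicate 2 the median was 0.21. Adjusted over the list alone 1 lymphocyte marker and 1 class II gene were higher. Camera gave an adjusted p of 0.193 and 0.998 on the edgeR counts. Without infarcted replicate 1 edgeR called 5 lymphocyte markers and 3 class II genes lower, and the lymphocyte list was called lower, with an adjusted p of 0.0133 where the range over the fits with a preset correlation was 0.0133 to 0.699. Without infarcted replicate 2 it called 1 class II gene higher and 0 lymphocyte markers lower, with 1 at an unadjusted p below 0.05 and 0 called by DESeq2. Without uninjured replicate 1 edgeR called 0 of either list, with 1 lymphocyte marker and 2 class II genes at an unadjusted p below 0.05 and 0 and 1 called by DESeq2. With uninjured replicate 2 left out it also called 0 of either, with 1 of each at an unadjusted p below 0.05 and 0 called by DESeq2; lymphocyte markers lay 1.20 higher on the log2 scale in infarcted replicate 1 than in infarcted replicate 2.

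**Figure D2:**
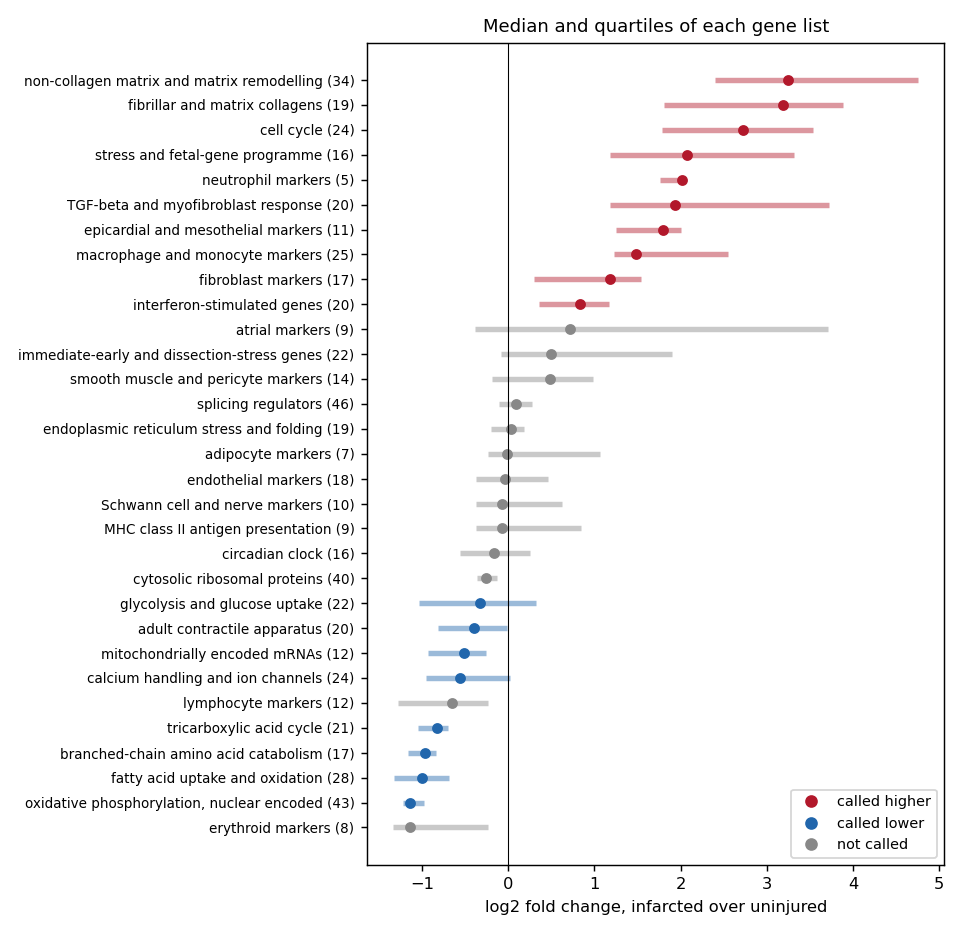
The median (point) and quartiles (bar) of the log2 fold change, infarcted over uninjured, of the members tested in each of 31 gene lists, with the number of members in brackets. The 10 lists called higher run from a median of 0.84 for interferon-stimulated genes to 3.25 for non-collagen matrix, and the 8 called lower from -0.32 for glycolysis to -1.13 for oxidative phosphorylation.

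The lists of endothelial, smooth muscle, Schwann cell and erythroid markers were not called. Endothelial markers had a median of -0.04, a mean of 0.04 and a downward test direction, with a median of 0.30 on library totals, and 1 of 18 was called, the water channel Aqp1, which fell by 0.82 ± 0.21; Cdh5, Erg and Egfl7 were not called, at 0.57 ± 0.22, 0.54 ± 0.21 and -0.53 ± 0.21. Smooth muscle and pericyte markers went both ways (median 0.48), 5 of 14 higher and 3 lower, with Mylk and Cspg4 up by 1.002 ± 0.20 and 0.95 ± 0.18 while Vtn and Kcnj8 fell by 1.12 ± 0.22 and 1.02 ± 0.20. Of 10 Schwann cell markers Pmp22 rose by 1.13 ± 0.20; Ngfr and Gfra3 were not called, at 0.73 ± 0.38 and -0.48 ± 0.42 (list median -0.07, mean 0.15, test direction upward; median 0.30 without infarcted replicate 1 and 0.06 without uninjured replicate 2). Of 8 erythroid markers 4 fell and 1 rose (median -1.14, or -1.76 without infarcted replicate 1 and -0.47 with the length trend removed); the globins Hba-a1, Hbb-bt, Hba-a2 and Hbb-bs fell by 1.70 ± 0.42, 1.21 ± 0.36, 1.14 ± 0.41 and 1.13 ± 0.31, and reads shared between these near-identical copies make the split among them uncertain. Counts adjusted over the list alone were 1 endothelial marker lower, 5 smooth muscle markers higher and 3 lower, 1 Schwann marker higher, and 4 erythroid markers lower and 1 higher. Camera called none of the 4 lists on the edgeR counts, with adjusted p of 0.816, 0.366, 0.878 and 0.0850. With uninjured replicate 2 left out edgeR called 0 members of any of the 4, with 3, 7, 1 and 3 at an unadjusted p below 0.05, and DESeq2 called 1, 8, 1 and 2. Without infarcted replicate 1 edgeR called 6 erythroid and 3 endothelial markers lower and called the erythroid list lower (adjusted p 7.41e-05, where fits with a preset correlation ranged from 7.41e-05 to 0.548); without infarcted replicate 2 it called 1 erythroid marker lower, and without uninjured replicate 1 it called 2 smooth muscle markers and 1 endothelial marker higher. Leaving out infarcted replicate 2 it also called 1 Schwann marker lower and 2 erythroid markers higher. Without uninjured replicate 1 it called 0 endothelial markers lower, with 4 at an unadjusted p below 0.05 and 2 called by DESeq2. Of the erythroid markers, edgeR called 0 without uninjured replicate 1, with 1 at an unadjusted p below 0.05 and 1 called by DESeq2, and 0 with the length trend removed, with 2 at an unadjusted p below 0.05.

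Epicardial and atrial markers, and single adipocyte markers, differed between the 2 infarcted libraries. Epicardial and mesothelial markers were called higher, with 4 of 11 members up and a median of 1.80: Aldh1a2, the retinoic acid enzyme, rose by 2.60 ± 0.28, Krt18 by 1.80 ± 0.43, Wt1 by 1.64 ± 0.27 and Tbx18 by 0.89 ± 0.27. The median member of the list lay 2.72 higher on the log2 scale in infarcted replicate 2 than in infarcted replicate 1, but of the called ones Aldh1a2 was at 36.9 CPM in infarcted 1 and 23.4 in infarcted 2, Wt1 at 12.6 and 9.80, Tbx18 at 1.03 times its infarcted 1 level in infarcted 2, and Krt18 at 1.44 and 3.08. Of 7 adipocyte markers the lipase Pnpla2 fell by 0.71 ± 0.26; Lipe, Cfd and Adipoq were not called, at -0.46 ± 0.38, 3.05 ± 2.70 and 2.12 ± 2.42 (list median -0.01, mean 0.57, test direction downward; median 0.01 without infarcted replicate 1, -0.98 without infarcted replicate 2 and 0.16 without uninjured replicate 2). Of 9 atrial markers tested Kcna5 rose by 0.72 ± 0.20 and Kcnj3 fell by 1.10 ± 0.19, while Nppa and Stard10 were not called, at 3.71 ± 1.20 and -0.69 ± 0.40 (list median 0.72, mean 1.90, test direction downward; median -1.03 without infarcted replicate 2 and -0.11 without uninjured replicate 1). Atrial myosin light chains were read almost only in infarcted replicate 2: Myl7 had 4, 5526, 13 and 20 counts and Myl4 had 67, 15123, 68 and 153 in infarcted 1 and 2 and uninjured 1 and 2. Sln, Mybphl and Bmp10 had 1457, 1123 and 58 counts there and at most 8 in any other library, and Nppa had 294, 1456, 86.9 and 46.7 CPM. Counts adjusted over the list alone were 4 epicardial markers higher, 0 adipocyte markers, and 1 atrial marker in each direction. Camera on the edgeR counts gave adjusted p of 0.0232, 0.641 and 0.878; the epicardial list had an adjusted p of 0.599 with an estimated correlation. Without infarcted replicate 2 the epicardial call ended (adjusted p 0.699, where fits with a preset correlation ranged from 1.39e-08 to 0.699, median -0.14, with 2 markers called higher and 2 lower), Cfd was at -2.72, and 4 adipocyte and 3 atrial markers and the adipocyte list (adjusted p 0.0345) were called lower. Adipoq had 0 counts in infarcted replicate 1 and 65 in infarcted replicate 2. The epicardial call also ended with library totals alone. Without infarcted replicate 1 the atrial and adipocyte lists were called higher (adjusted p 1.60e-20 and 0.00603, the ranges over such fits being 1.60e-20 to 0.955 and 0.00603 to 0.823), and 10 epicardial, 4 atrial and 2 adipocyte markers were. With uninjured replicate 1 left out edgeR called 0 adipocyte markers lower and 0 atrial markers higher, with 1 and 2 at an unadjusted p below 0.05 and 1 and 1 called by DESeq2. Without uninjured replicate 2 edgeR called 0 members of the 3 lists, with 4, 0 and 3 at an unadjusted p below 0.05 and 2, 0 and 1 called by DESeq2.

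**Figure D3:**
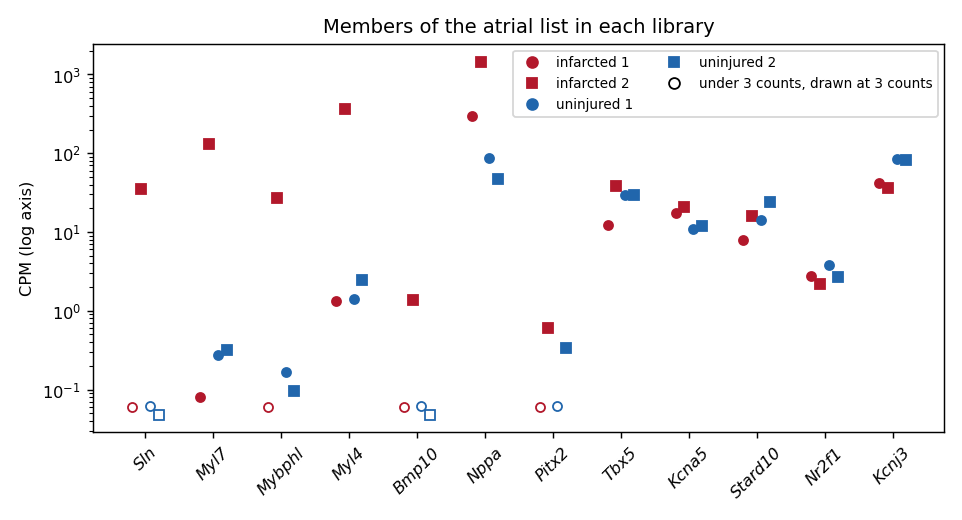
CPM on a log axis of the 12 atrial markers in each library, red for infarcted and blue for uninjured, circles for replicate 1 and squares for replicate 2; open symbols are under 3 counts and drawn at that floor. Sln, Myl7, Mybphl, Myl4 and Bmp10 stand over 10-fold above every other library in infarcted replicate 2.

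Splicing regulators were not called as a group. Of 46 tested 3 rose and 3 fell, with a median log2 fold change of 0.09 and a camera adjusted p of 0.998 on the edgeR counts, and the counts adjusted over the list alone were the same. The polypyrimidine tract-binding proteins Ptbp1 and Ptbp3 rose by 1.19 ± 0.19 and 0.93 ± 0.20, Ptbp1 to 80.2 ± 12.6 from 35.1 ± 2.58 CPM (SD, n = 2), while the muscle regulators Rbfox1 and Rbm38 fell by 1.52 ± 0.23 and 1.03 ± 0.20. Without uninjured replicate 2 edgeR called 0 of the 46, with 3 higher and 4 lower at an unadjusted p below 0.05 and 1 and 2 called by DESeq2; without uninjured replicate 1 it called 5 higher.

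Inclusion was tested for 8083 alternative exons and splice sites in 3947 genes, with a median of 58 reads per event and library. edgeR called 0 events higher and 0 lower, with 530 at an unadjusted p below 0.05 (194 higher and 336 lower) where chance gives 404, and a smallest adjusted p of 0.744. The other 2 splits of the 4 libraries gave 259 and 297, and the infarcted and uninjured libraries did not overlap for 38.4% of events, where chance gives 33.3%. DESeq2 called 0 as well, with 332 at an unadjusted p below 0.05. Limma called 0 without weights (598 unadjusted) and 0 with weights that allow for overdispersion (771 unadjusted, smallest adjusted p 0.141). In simulated data edgeR recovered 0 of 50 events changed by 40 percentage points, and the overdispersed limma fit recovered 36, where the simulation used the model of that limma fit and so favours it. That limma fit, DESeq2 and those named next were tried after edgeR had given 0. With the overdispersion set to 0 or 0.003, below the estimate of 0.0101, limma called 31 higher and 59 lower or 9 and 18, and with 0.03 it called 0 (705 unadjusted). Limma with binomial weights called 58 higher and 121 lower, but in simulation it made 45 false calls beside 54 true ones, and it called 12 and 8 events in the other 2 splits of the 4 libraries. Of the 530 events 63.4% were lower (95% binomial interval over events 59.1% to 67.5%), and without infarcted replicate 2 the share was 48.0% (43.1% to 52.9%). These intervals treat events as independent although all come from the same libraries, so they leave out the spread between mice.

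Among the genes with splicing known in the heart, the 4 events with the smallest p in edgeR were not called by it. A 475-nucleotide exon of Pkm2 (chromosome 9, 59523375 to 59523849, mm9) was included at 9.98% ± 0.127 in infarcted and 0.820% ± 0.354 in uninjured hearts (SD, n = 2). Pkm2 is here the symbol of the muscle pyruvate kinase gene, and its isoforms were not told apart. A 113-nucleotide exon of Capzb, an actin-capping protein (chromosome 4, 138844776 to 138844888), was at 70.1% ± 2.57 against 87.4% ± 1.42. A 30-nucleotide exon of cardiac troponin T (Tnnt2, chromosome 1, 137740362 to 137740391) was at 2.43% ± 0.304 against 0.455% ± 0.120, and a 126-nucleotide exon of Tpm1 (chromosome 9, 66895593 to 66895718) at 99.7% ± 0.0566 against 99.9% ± 0.00707. edgeR gave each an adjusted p of 0.744. Of 306 events tested in 58 genes of that list 51 had an unadjusted p below 0.05, and 35 of these were lower. Further exons, chosen after their values were seen, included a 48-nucleotide exon of Rpn2 (chromosome 2, 157148959 to 157149006) at 35.2% ± 2.40 against 62.0% ± 1.05, a 24-nucleotide exon of the transcription factor Mef2a (chromosome 7, 74389407 to 74389430) at 40.4% ± 4.01 against 71.4% ± 3.69, and a 33-nucleotide exon of Snap23 (chromosome 2, 120416399 to 120416431) at 30.5% ± 6.87 against 65.9% ± 1.92. Of the 15 exons in the plot of inclusion levels, edgeR, DESeq2 and limma with the estimated overdispersion called 0. Limma with an overdispersion of 0.003 called 13, those of Tnnt2 and Tpm1 being left out, and with 0 or with binomial weights it called 15. Since edgeR called no event, the overlap of genes changed in level with genes changed in splicing has no odds ratio.

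**Figure D4:**
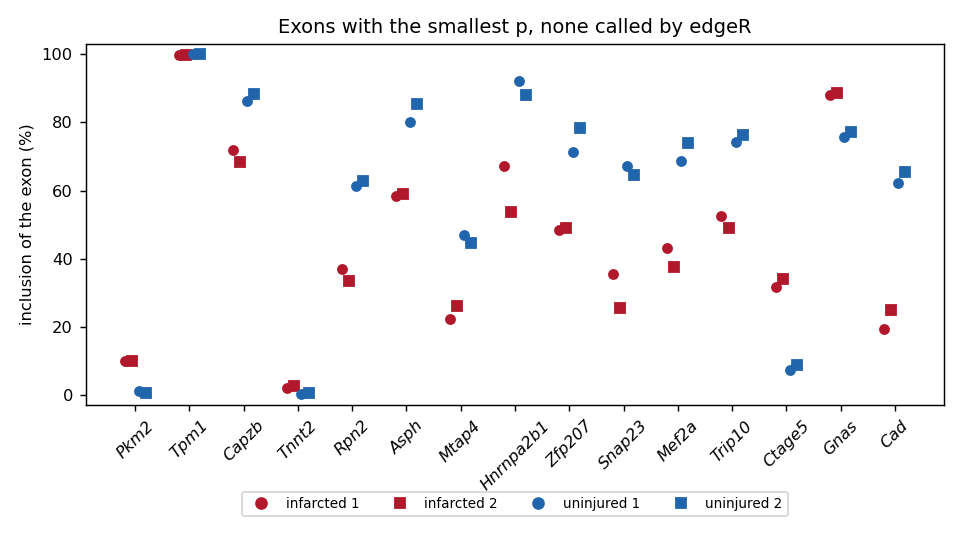
Percent inclusion of 15 exons in each of the 4 libraries, red for infarcted and blue for uninjured, circles for replicate 1 and squares for replicate 2. The first 4 are those of the heart splicing list with the smallest p and the others were chosen after their values were seen; none was called by edgeR, and the Capzb exon lies at 71.9% and 68.2% in infarcted against 86.4% and 88.4% in uninjured hearts.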

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

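Microexons, very short exons that are often specific to nerve or muscle, form a class of 479 events that the splicing comparison does not use. They had a value in 371 and 377 cases in infarcted replicates 1 and 2 and in 0 and 0 cases in uninjured replicates 1 and 2. Of 206 with at least 10 reads in both infarcted libraries 63 also had over 3 inclusion reads in each. Among them, chosen after their values were seen, a 9-nucleotide exon of cardiac troponin T (Tnnt2) was included at 81.85% and 82.85% and a 12-nucleotide exon of the same gene at 42.4% and 47.95%. They are given because the uninjured libraries hold no value for any of the 479 events. Whether this class was measured in the uninjured libraries is not given in the sources used here, so the missing values are not read as a lower level and no difference was tested. Another 11 events of other classes lacked values in both uninjured libraries but had at least 10 reads in both infarcted ones.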

How the results depend on the processing

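Alternatives added after the data were seen were library totals as the scale, the length, GC and mitochondrial corrections, legacy=FALSE, DESeq2 with a library left out, and the splicing fits with weights, DESeq2 or thinned reads. Genes called higher and lower numbered 2496 and 2146 with RLE factors, 2469 and 2078 with upper-quartile factors, 2656 and 2233 without a filter, 1767 and 1599 at 5 CPM or more (fewer genes tested), 2299 and 2095 in DESeq2, 2458 and 1837 in limma-voom, 2511 and 1997 with legacy=FALSE, 2544 and 2012 without mitochondrially encoded genes, 2764 and 2111 with the GC trend removed, and 2530 and 1722 with the length trend removed, of which 2221 and 1425 were calls of the edgeR fit without the correction. The setting legacy=TRUE is the default used here. A 2-fold threshold gave 1765 and 769, and library totals gave 4386 and 786, the scale itself moving by the shift in the median of all genes. Leaving out a library gave 102 to 2144 higher and 8 to 1824 lower, the lowest without uninjured replicate 2, each such fit having 1 residual degree of freedom in place of 2; why that library mattered most was not tested. The lone library of a group is then assumed to vary like the others. DESeq2 called 1343 and 1179 without infarcted replicate 1, 1280 and 861 without infarcted replicate 2, 1798 and 1743 without uninjured replicate 1, and 1167 and 600 without uninjured replicate 2; the cause was not tested. Lists called higher and lower, 10 and 8, were 0 and 0 with an estimated correlation and 3 and 0 with fry, and in other settings 8 to 12 and 6 to 10. With library totals the lymphocyte and erythroid lists were called lower (adjusted p 0.0385 and 0.0197, of ranges 0.0133 to 0.699 and 7.41e-05 to 0.548 over fits with a preset correlation). edgeR called 0 splicing events under each setting run, with 307 to 584 at an unadjusted p below 0.05, where limma called 31 higher and 59 lower with an overdispersion of 0, 9 and 18 with 0.003, and 58 and 121 with binomial weights. The alternatives for the overlap of gene and splicing calls were not run, since no event was called by edgeR. Of 133 named genes 113 were called. Their calls were lost for 0 to 4 genes with other factors, filters, DESeq2, limma-voom, legacy=FALSE, mitochondrially encoded genes left out or the GC trend removed, 15 at 2-fold, 11 with library totals, 12 with the length trend removed, and 9, 13, 22 and 92 without infarcted 1, infarcted 2, uninjured 1 and uninjured 2. Of those not called, Adipoq was at -0.21 in limma-voom, and Rpl38 and Rps15 were at 0.40 and 0.31 with the length trend removed. With 1 library left out Cfd ran from -2.72 to 4.90 and Adipoq from -6.23 to 4.10, that lowest value being a fitted one against a lone infarcted library with 0 counts. With the replicate block edgeR called 2950 and 2340 genes, 11 and 9 lists and 0 and 0 splicing events (458 unadjusted), with the immediate-early list called higher (adjusted p 0.00236) and the erythroid list lower (0.0387). Nothing in the labels says that the numbers pair the mice, so they are not taken to do so. Deviations of libraries with the same number had a correlation of 0.108, over 2 pairs only, and -0.108 with the numbers crossed. The second value is the negative of the first by construction, so neither decides whether mice are paired. With the real reads of each event, whose median was 58 per event and library, edgeR recovered 0 of 50 simulated changes of 40 percentage points.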

Other observations

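Of the tests below, the comparison of oxidative phosphorylation genes with matched lists was written before its result was seen, and the other tests of explanations were chosen after the results were seen. Among clock genes the repressors Per1 and Per2 rose by 2.49 ± 0.24 and 2.10 ± 0.29 (log2 ± SE), and the clock-controlled genes Dbp and Hlf and the repressor Nr1d1 fell by 1.03 ± 0.21, 0.95 ± 0.24 and 0.84 ± 0.22. In all 2 of 16 were higher and 4 lower, and 2 and 4 adjusted over the list alone. The list had a median of -0.16 (0.20 with library totals), a mean of 0.02, a downward test direction and a camera adjusted p of 0.679. Without uninjured replicate 2 edgeR called 1 higher and 0 lower, with 2 and 5 at an unadjusted p below 0.05 and 2 and 3 called by DESeq2, and without uninjured replicate 1 it called 2 lower. Of 22 immediate-early and dissection-stress genes 7 rose and 0 fell, the same as adjusted over the list alone, with a median of 0.49: the transcription factors Fosb, Myc and Klf6 by 2.11 ± 0.47, 2.09 ± 0.24 and 1.17 ± 0.20, and Ier3 by 1.19 ± 0.21. Their level was 0.91 higher in infarcted replicate 1 than in infarcted replicate 2 and 0.63 higher in uninjured replicate 1 than in uninjured replicate 2. The camera adjusted p was 0.0566, in a range of 3.21e-07 to 0.661 over fits with a preset correlation, and the list was called higher without infarcted replicate 2 (3.21e-07) or uninjured replicate 1 (0.00482) and with the length or GC trend removed (0.0127 and 0.0368). Without uninjured replicate 2 edgeR called 0 members, with 6 higher and 2 lower at an unadjusted p below 0.05 and 5 and 2 called by DESeq2, and without infarcted replicate 1 it called 3 lower, the list median being -0.17 with 12 of 22 members below 0.

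Genes of protein folding in the endoplasmic reticulum were not called as a list. Of 19 genes the disulfide isomerase Pdia4 and asparagine synthetase Asns rose by 0.78 ± 0.19 and 0.96 ± 0.31, while Herpud1 and Dnajb9, which act in disposal and folding of misfolded proteins, fell by 0.83 ± 0.20 and 0.64 ± 0.19, and the counts adjusted over the list alone were 2 and 2. The median and mean were both 0.03, the median -0.04 without infarcted replicate 1 and -0.16 without uninjured replicate 1, the test direction downward and the camera adjusted p 0.878. edgeR called 0 of them without infarcted replicate 1, with 2 lower at an unadjusted p below 0.05 and 1 lower called by DESeq2, and 0 without uninjured replicate 2, with 3 higher and 2 lower unadjusted and 2 lower called by DESeq2. It called 1 in each direction without uninjured replicate 1, 1 lower without infarcted replicate 2, and 4 higher and 1 lower with the length trend removed. Of 40 ribosomal protein genes Rpl3 rose by 0.995 ± 0.26 and Rpl15 fell by 0.58 ± 0.20, Rpl38 and Rps15 were not called, at -0.44 ± 0.22 and -0.46 ± 0.23, and adjusted over the list alone 0 were called, with 1 in each direction at an unadjusted p below 0.05. Paralogs and pseudogenes that share reads with these short mRNAs make single values uncertain. Their median was -0.26, but 0.24 with the length trend removed, 0.09 with library totals and 0.06 without uninjured replicate 2, a library in which they lay 0.52 higher than in uninjured replicate 1. Camera gave an adjusted p of 0.0566, which over the fits with a preset correlation went as high as 0.998. It called the list lower without uninjured replicate 1 (median -0.49) and without infarcted replicate 2 (median -0.35), with 38 of 40 members below 0 in each.

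All 43 nuclear-encoded oxidative phosphorylation genes were lower in infarcted hearts, with a median log2 fold change of -1.13. Lists matched on transcript length and expression had a median of -0.638 and a lowest value of -0.974. The genes lay -0.497 from the matched median, and 0 of 10000 lists were as low. They thus fell further than genes of like length and expression, but that count overstates the evidence against the length trend as the whole cause. Random lists draw genes independently, whereas these members move together (estimated inter-gene correlation 0.972). More of the fall was shared with matched lists than not. As only the 43 members were kept out of the matching, that shared part cannot be laid to length alone. Uninjured replicate 2 alone stays open: without it the upper quartile was -0.714, but a value below 0 was bound to follow from groups that did not overlap in any of the 43, edgeR called 0 of them where DESeq2 called 39, and the list lay 0.63 higher in that library than in the other uninjured one. A lower share of cardiomyocyte RNA stays open too: the list lay -0.743 from the contractile genes (95% bootstrap interval -1.10 to -0.34), but with the length trend removed, a comparison added after the first value was seen, the difference was -0.23 (-0.55 to 0.13). Both bootstrap intervals resample genes as if independent and leave out the spread between mice. The infarct itself stays among the open explanations, untested.

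Collagen mRNA was higher by a median of 3.19 on the log2 scale. A lower share of cardiomyocyte RNA would raise every other cell type alike, yet collagens lay 3.23 above endothelial markers (95% bootstrap interval over genes 1.86 to 4.02). More fibroblasts with the same expression per cell would raise their markers as much, yet collagens lay 2.32 above 15 fibroblast markers found in no other list (0.91 to 3.28), whose median was 0.87. Bootstrap intervals here resample genes as if independent, although the collagens moved together (estimated inter-gene correlation 0.715). They leave out the spread between mice and alone exclude neither explanation. With each library left out in turn, the collagen median ran from 2.98 to 3.28 and the endothelial median from -0.08 to 0.003. Scar or border tissue in the samples stays open, because the contractile list had a median of -0.392 (-0.79 to -0.04). That value depends on the scale, being -0.0396 with library totals. A response of remote myocardium to the infarct also stays open, and no test here tells it from that tissue.

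Infarcted replicate 2 held atrial mRNAs, Myl4 at 360 CPM and Myl7 at 132 CPM against 1.34 and 0.0800 CPM in infarcted replicate 1. Over 10-fold above each other library were 5 of 12 atrial markers against 24 of 21540 other genes (Fisher's exact test over genes, two-sided p 2.41e-12, 7.24e-12 adjusted over 3 lists). In the same test the adipocyte list had 1 of 12 (p 0.0160, adjusted 0.0240), and the epicardial list had 0 of 11. The test was chosen after the atrial mRNAs had been seen in this library, so its p restates that observation. Atrial tissue in that sample is a candidate explanation. Of 6 atrial markers over 10-fold above both uninjured libraries there, 1 was above both in infarcted replicate 1, Nppa, which argues against a switch in both hearts for the other 5 and leaves it open for Nppa. This count was made over 3 sets of genes after the values were seen, with 0 of the first 5 markers and 2 of all 12, Nppa and Kcna5, the latter count alone excluding nothing. A response of that heart alone and other tissues stay open, since Chad, Epyc and Mmp3, matrix genes chosen after their values were seen, had 506, 161 and 1047 counts there against at most 34, 5 and 151 elsewhere, and Nppa, Myl4, Myl7 and Mybphl are also on the stress list and Kcna5 and Kcnj3 on the channel list.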
